A study of Caenorhabditis elegans with 4 samples.

How the data were processed

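Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans worms at the L3 larval stage, of mixed sex per the labels. The worms were of strain OP186, which carries the integrated transgene wgIs186 in an unc-119(ed3) background. The transgene makes UNC-39, a SIX-family homeodomain protein, with GFP and FLAG fused to its C terminus. Per the labels, the chromatin was sheared with a microtip sonicator and the antibody entry reads unc-39; whether it recognised the tag or the protein itself is not given in the sources used here. There were 4 biological replicates of 1 group, numbered as in the labels, and no second group, so no test between groups was made. A control experiment is named in the labels and was not analysed here.

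The files were peak lists in narrowPeak format on the ce10 and ce11 genome assemblies. Per the deposited README files, each replicate had a relaxed list of peaks and background. Per the same files, a pooled relaxed list was made from the alignments of all 4 replicates with a control. A thresholded list was made from the pooled and replicate lists by the irreproducible discovery rate (IDR), a method based on how alike replicates rank peaks. The peaks of the thresholded list are called reproducible peaks here, a name that does not mean that every replicate ranked each of them alike. The aligner, the peak caller, the threshold and their versions are not given in the sources used here. The signal of each peak is the authors' own value as deposited, computed with a control, and was used only to rank peaks within a list. The deposited q-value column was read as −log10 of q by the convention of the format, since its scale is not spelled out in the files. Read depth is unknown, because the files hold peaks and no read counts. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error over peaks only. Peaks of the pooled list are not independent replicates, and a test over peaks or genes describes this pooled list and not the spread between worm cultures.

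The ce11 lists were used throughout, with ce10 counts as an alternative, and no coordinates were carried between assemblies. Peak ends were compared with the chromosome lengths of the WBcel235 reference sequence, which is the same assembly as ce11, and 0 peaks ended beyond a chromosome. Genes came from Ensembl release 115, and names of mitochondrial genes from the RefSeq gene table of WBcel235. Coordinates are 1-based. A peak was assigned to every protein-coding gene whose transcript start lay within a window from 1000 bp upstream to 200 bp downstream of the start, measured at the summit. Each summit was placed in the first class that applied among promoter, exon, intron, within 1000 bp of a non-coding gene only, and other intergenic sequence.

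The tests, alternatives, 13 gene lists and rule for named genes were fixed before the data were examined. The lists covered body wall muscle, pharynx, pan-neuronal genes, neurotransmitters and neuropeptides, the SIX-network and mesodermal regulators, homeobox genes, intestine, epidermis and cuticle, germline, cytosolic ribosomal proteins, glycolysis and energy metabolism, heat shock and proteostasis, and translation factors and splicing. They held 547 names in total, of which 7 had no gene in the annotation. Named genes were those assigned to the 20 reproducible peaks with the highest signal (or the nearest protein-coding start), up to 4 members of each list with a reproducible promoter peak in order of signal, and unc-39 and unc-119. The 20 strongest peaks were all mitochondrial, so the 20 strongest nuclear peaks were added after this was seen; other genes named were chosen after their values were seen, and so were all values for nuclear peaks only.

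Support by a replicate was the share of reproducible peaks overlapped by at least 1 bp by its list or by its 1000 strongest peaks, against 1000 draws of as many peaks from the pooled list. Pairs of replicates were compared by the shared share of their 500 strongest peaks, mean of both directions, against 1000 random draws, and by Spearman's rho of signal over pooled peaks found in both. Position classes, chromosomes and gene lists were tested with two-sided Fisher's exact tests of reproducible against other pooled peaks, with the 3839 protein-coding genes with a pooled promoter peak as the background for lists. The rank of list members' strongest promoter peak was tested by a two-sided permutation test with 100000 draws. The Benjamini-Hochberg adjustment ran over the 13 lists, 5 classes, 7 chromosomes (or the nuclear chromosomes alone) and 2080 6-mers. For the strongest nuclear peaks of each replicate alone it ran over the 4 replicates.

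The SIX-type motifs TCAGGTTTC (up to 1 mismatch) and TGATAC, and all 6-mers on both strands, were searched within 50 bp of the summit and in a pair of windows of the same width centred 300 bp to either side. The planned exact sign test set the summit window against the mean of the pair. On simulated sets of 500 genomic windows with no planted site, that sign test called a difference in 60% of sets, because a rare motif is found more often in a pair of windows than in a single window. An exact permutation of the 3 windows within each peak was therefore added after the planned test had been run; it called 7% of the same sets, and 100% of sets with the site planted in 16 of 86 peaks. In simulated data on the 3839 genes, the list of ribosomal protein genes (43 genes, the longest tested) was raised by 1 SD. The permutation test of ranks called it in 100% of runs and an unchanged list in 0.417%. Fisher's test called them in 75% and 0.208%. A raised shorter list was not simulated, so these shares do not hold for the shorter lists, where a test calls a like change less often.

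Alternatives were other promoter windows, overlap rules, numbers of top peaks, backgrounds, motif windows and locus widths, the ce10 lists, the upper part of the reproducible list by signal, the 500 strongest pooled peaks, each replicate left out in turn where replicate lists entered, and nuclear peaks only. The pooled and thresholded lists could not be remade without a replicate. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and fixed random seeds.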

Results

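UNC-39 occupancy was measured by ChIP-seq in 4 biological replicates of whole L3 larvae carrying a tagged copy of the protein, a SIX-family homeodomain regulator. The relaxed lists held 30000 peaks in replicates 1 and 2, 13225 in replicate 3 and 29529 in replicate 4, and the pooled relaxed list held 12797. The lowest signal in each list was 5.54, 6.57, 2.00 and 2.00 in replicates 1 to 4, and signal was used only for ranks within a list; replicates 1 and 2 end at 30000 peaks, so their lowest values depend on where the list ends. Taking the deposited column as −log10 of q, the median q-value was 0.748, 0.850, 0.00710 and 0.232 in replicates 1 to 4 and 0.931 in the pooled list. In replicate 3 every peak passed 0.05 by that column, with a lowest −log10 q of 1.37. The relaxed lists, deposited as peaks and background together, were read here as rankings of places.

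The thresholded list held 110 reproducible peaks on ce11, of which 24 (21.8%, 95% exact interval 14.5 to 30.7) lay on the mitochondrial genome and 86 on nuclear chromosomes. The mitochondrial peaks were by far the highest in signal, with a median of 580 (78.3 to 2853) against a nuclear median of 50.5 and a nuclear maximum of 95.5. The 23 strongest peaks were all mitochondrial, and all 24 mitochondrial peaks of the pooled list were reproducible peaks. The highest lay in ND5, a subunit gene of respiratory complex I (positions 12163 to 12702, signal 2853), followed by ND4 (7079 to 7314, signal 1485), COX3 (5689 to 6360, signal 1341), CYTB (4469 to 4915, signal 1143) and ATP6 (2860 to 3115, signal 1100). In total 21 mitochondrial summits lay in protein-coding genes and 3 in rRNA genes. Mitochondrial peaks covered 7327 of the 13794 bp of that genome (53.1%), against 0.0312% of the nuclear genome for the nuclear peaks. The list was the top of the pooled list: 110 of 110 peaks matched it in rank, summit and signal within 1e-09. By the q column, 41 of the 110 peaks, all of them nuclear, did not pass 0.05 (median q 0.0448). The list includes 2 mitochondrial pairs that share a start and end and differ in summit.

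**Figure D1:**
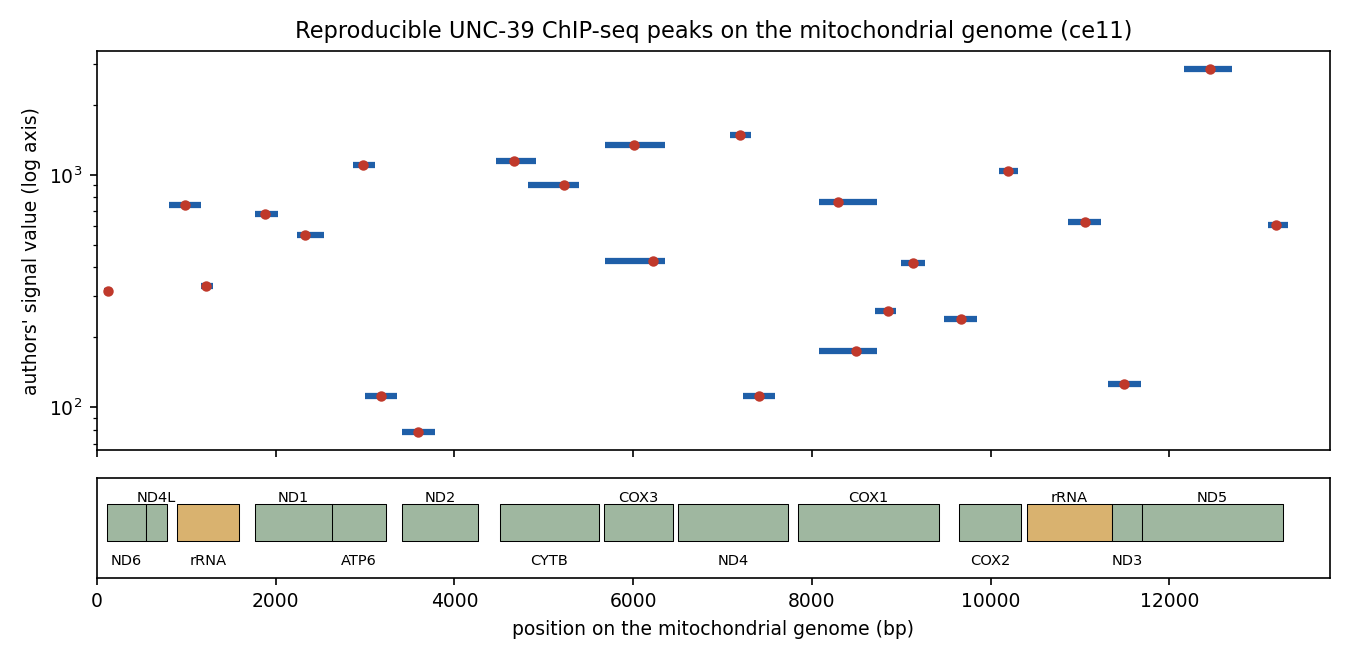
Reproducible peaks along the mitochondrial genome on ce11 (position in bp, horizontal) against the authors' signal value (log axis, vertical), with the summit of each peak as a red point, its extent as a blue bar, and protein-coding (green) and rRNA (tan) genes drawn to scale below. The 24 peaks are spread along the genome, and the highest, at signal 2853, lies in ND5.

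The 5 strongest nuclear peaks lay on the X chromosome outside promoter windows, while of the 20 strongest 9 were on X. The highest was in an intron of mom-1, which acts in Wnt secretion (X, 6296392 to 6296755, signal 95.5), with the nearest protein-coding start, that of cest-16, 3368 bp away. Intergenic peaks on X nearest to F55G7.5 (11937384 to 11937747, signal 94.7), W02H3.3 (11093982 to 11094345, signal 91.0), ZK899.6 (9465654 to 9466017, signal 90.03) and K02D3.1 (13700657 to 13701020, signal 87.2) came next. The following pair lay on autosomes in the promoter windows of H41C03.3 (II, 5844676 to 5845039, signal 84.5) and egg-5, a gene of the egg-to-embryo transition (I, 4172005 to 4172368, signal 84.0); the summits were within 300 bp of sls-2.1 and sls-2.4, genes for spliced leader RNAs. Among the 20 strongest nuclear peaks, promoter peaks were also found at ain-1, a component of the microRNA machinery (signal 71.1), cdc-48.1, an AAA ATPase of protein turnover (69.7), the ribosomal protein genes rpl-15 (67.5) and rpl-3 (64.6), tasp-1 (63.5), drap-1 (62.1), Y39B6A.43 (60.7) and Y75B8A.23 with tim-1 (58.5). The remainder comprised intronic peaks in pqn-41 (71.0) and dhc-4, nearest to col-94 (67.6), intergenic peaks nearest to F22H10.2 (67.98) and sma-9, a regulator of BMP signalling (58.1), and a peak beside a tRNA gene nearest to ets-5 (58.7).

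Replicates differed in where they ranked these peaks. The mom-1 peak was ranked 39, 21, 225 and 63 in replicates 1 to 4, and the rpl-3 peak 121, 5368, 32 and 50. Of the 110 reproducible peaks, 98.2%, 92.7%, 90.9% and 97.3% were overlapped by the relaxed lists of replicates 1, 2, 3 and 4. The share in the 1000 strongest peaks was 77.3% (exact interval 68.3 to 84.7) in replicate 1, 66.4% (56.7 to 75.1) in replicate 2, 74.5% (65.4 to 82.4) in replicate 3 and 78.2% (69.3 to 85.5) in replicate 4. Random pooled peaks gave means of 4.33% to 7.16%, and p was 0.001 in each replicate, the smallest that 1000 permutation draws can give. In all 4 replicates at once, 35 of the 110 peaks (31.8%, 23.3 to 41.4) were among the 1000 strongest, made up of 20 of 24 mitochondrial and 15 of 86 nuclear peaks (17.4%, 10.1 to 27.1). Without replicate 2 the count was 56, and 33 of the nuclear peaks, though leaving out a replicate can only keep or raise it. The reproducible list was made from these libraries, so its overlap with them is not independent evidence.

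**Figure D2:**
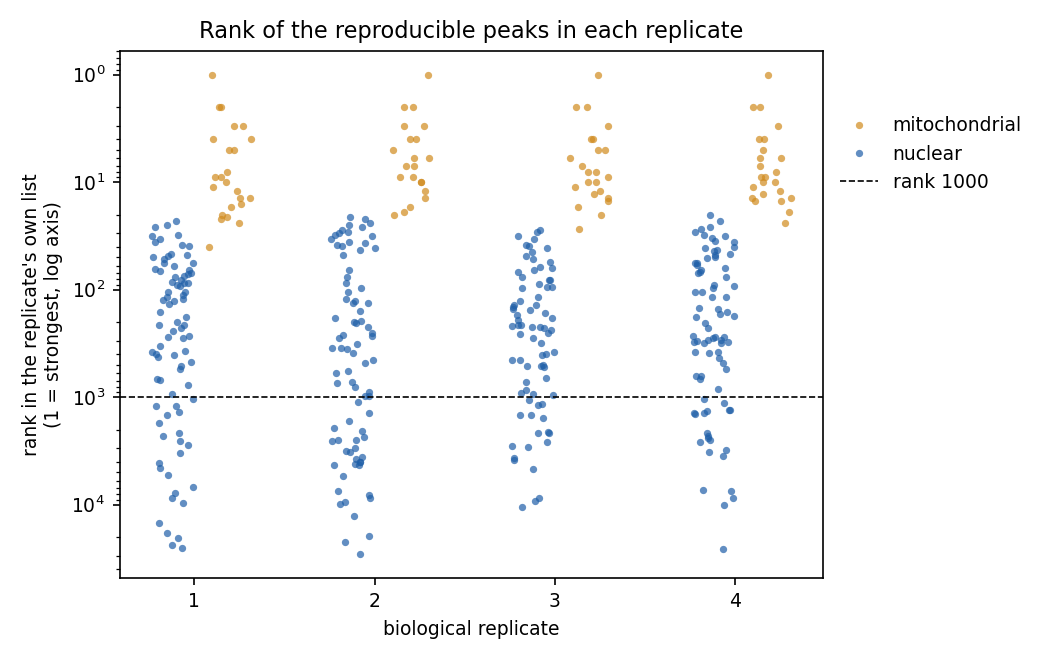
Rank of each reproducible peak in the list of each biological replicate (log axis, 1 is the strongest), with mitochondrial peaks in orange, nuclear peaks in blue and a dashed line at rank 1000; peaks with no overlap in a replicate are not drawn. Mitochondrial peaks hold the top ranks in all 4 replicates, while nuclear peaks spread from the top ranks to beyond rank 1000.

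Overlap between replicates was low, though above chance. Among the 100 strongest peaks of each replicate, which include the mitochondrial peaks, the mean shared part was 33.5%, and among the 100 strongest nuclear peaks it was 15%. On average 13.9% ± 4.04 (SD over 6 pairs of replicates) of the 500 strongest peaks were shared, from 9.80% for replicates 2 and 3 to 20.1% for replicates 3 and 4. Random draws shared 0.581% on average and 2.20% at most, and p was 0.001 for each of the 6 pairs, the smallest that 1000 permutation draws can give. With nuclear peaks only the mean was 10.1% ± 3.91. Over pooled peaks found in both replicates of a pair, Spearman's rho of signal averaged 0.12 (SD 0.10 over 6 pairs), from 0.01 over 6130 peaks in replicates 1 and 2 to 0.28 over 1705 peaks in replicates 3 and 4; these are correlations across peaks, which are not independent. The mean was 0.06 without replicate 3 and 0.19 without replicate 2. Among the 2000 strongest pooled peaks the mean was 0.15 (SD 0.16 over 6 pairs), from -0.08 in replicates 1 and 2 to 0.39 in replicates 3 and 4.

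**Figure D3:**
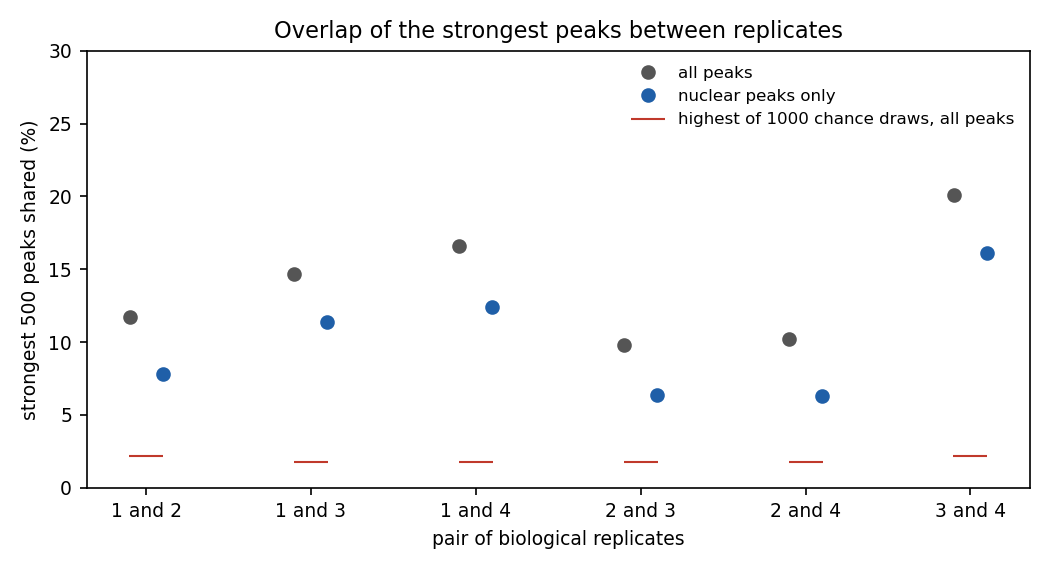
Share of the 500 strongest peaks in common (percent, vertical) for each pair of biological replicates (horizontal), for all peaks (grey) and nuclear peaks (blue), with red bars at the highest of 1000 chance draws. Every pair lies above the chance draws, and replicates 3 and 4 share most, at 20.1%.

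Promoters held more of the reproducible peaks, and exons fewer, than of the other pooled peaks. Summits lay in promoter windows for 57 of 110 reproducible peaks (51.8%) against 29.8% of the 12687 others (Fisher's exact test, adjusted p = 4.25e-06). The 110 include 24 mitochondrial peaks and the others include 0. On that short genome a promoter window reaches into neighbouring genes, so the values for nuclear peaks only, given below, are the like comparison. Exonic summits made up 8 of 110 (7.27%) against 28.1% (exact test, adjusted p = 4.29e-07). Summits near non-coding genes only made up 16 of 110 (14.5%) against 6.35% (exact test, adjusted p = 0.00395). Introns (15.5% against 23%, adjusted p = 0.0848) and other intergenic sequence (10.9% against 12.8%, adjusted p = 0.667) did not pass the exact test. The lower share in introns passed with a promoter window of 500 bp (exact test, adjusted p = 0.0190) and against the relaxed lists of replicate 3 (adjusted p = 0.0417) and replicate 4 (adjusted p = 0.0193), and not among nuclear peaks only (19.8%, adjusted p = 0.746). Among the 86 nuclear peaks, 38 were in promoters (44.2%, adjusted p = 0.0102), 3 in exons (3.49%, adjusted p = 3.70e-08) and 16 near non-coding genes only (18.6%, adjusted p = 2.57e-04) by the same exact test. Over all 110 peaks, the excess near non-coding genes was lost with a promoter window of 2000 bp (9.09%, exact test, adjusted p = 0.0589). In the upper 55 peaks by signal the share was 1.82%, below that of other peaks (exact test, adjusted p = 0.327). Both settings count the 24 mitochondrial peaks, all of which are in the upper 55. All 16 summits of this class were nuclear, so the mitochondrial peaks lower these shares. They are not like the nuclear value.

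Cytosolic ribosomal protein genes carried more reproducible promoter peaks than other genes, and no other list passed the test. A reproducible peak lay in the promoter of 6 of 43 ribosomal protein genes (13.95%) against 52 of 3796 other genes (1.37%; odds ratio 11.7, Fisher's exact test, adjusted p = 4.70e-04). The highest were at rpl-15 (IV, 654733 to 655096), rpl-3 (III, 3867423 to 3867786), rps-1 (III, 4475466 to 4475829, signal 57.98) and rpl-35 (III, 7854518 to 7854881, signal 55.9), with summits 249 to 434 bp upstream of the start; the others were rpl-20 and rpl-11.2. Among the 86 strongest nuclear peaks of each replicate alone, 2 of 49, 0 of 36, 5 of 44 and 5 of 67 ribosomal protein genes had a promoter peak in replicates 1 to 4 (exact test, adjusted p = 0.0403, 1, 2.75e-04 and 6.57e-05). The excess passed in every replicate but replicate 2. There only 0.411% of other genes had such a peak, so 0 of 36 was a likely count and decides neither way. In the energy metabolism list 1 of 21 genes had such a peak, cox-5A, a subunit of cytochrome c oxidase (signal 46.3, exact test, adjusted p = 1). In the translation and splicing list it was 1 of 18, iff-2, an initiation factor 5A gene (signal 55.0, exact test, adjusted p = 1). No gene had a reproducible promoter peak among 15 tested for body wall muscle, 5 for pharynx, 14 pan-neuronal, 5 for neurotransmitters and neuropeptides, 8 of the SIX-network and mesoderm, 12 homeobox, 5 for intestine, 10 for epidermis and cuticle, 7 for germline and 17 for heat shock. For each of these 10 lists the exact test gave an unadjusted p of 1. It could hardly give less, because about 1.51% of other genes had such a peak and 0 was the likely count in lists this small. The 0 counts are therefore no evidence that these genes lack binding. Only genes with a pooled promoter peak were tested, which were 8 of 30 names of the SIX-network and mesoderm and 12 of 78 homeobox names.

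By signal rank, the promoter peaks of ribosomal protein genes also stood high. These ranks come from the same pooled list and include the 6 genes with a reproducible peak, so they are not independent support. Over the whole list of ribosomal protein genes the values were as follows. Their strongest promoter peaks had a mean percentile of 70.03 (median 75.5, 43 genes; permutation p = 1e-05, the smallest that 100000 draws can give; adjusted p = 1.30e-04). Energy metabolism genes had a mean percentile of 64.6 (21 genes, permutation p = 0.0193, adjusted p = 0.126) and intestinal genes one of 24.12 (5 genes, permutation p = 0.0425, adjusted p = 0.184), neither of which passed after adjustment. With a promoter window of 2000 bp the energy metabolism list passed (mean 68.5, permutation, adjusted p = 0.00819), beside a ribosomal protein mean of 65.7 (adjusted p = 9.10e-04). The SIX-network and mesoderm list had a mean of 49.4 but a median of 67.5 (8 genes, permutation, adjusted p = 0.968), and homeobox genes a mean of 42.6 (12 genes, adjusted p = 0.647). The other lists had means of 42.96 to 62.4, with adjusted p from 0.647 to 0.968. Replicates differed in this result: ranked in one replicate alone, ribosomal protein genes had means of 62.3, 54, 69.8 and 63.6 in replicates 1 to 4 (permutation, adjusted p = 0.0267, 0.750, 6.50e-04 and 0.00195). One other list passed in a single replicate, heat shock and proteostasis in replicate 1 (mean 67.7, 20 genes, permutation, adjusted p = 0.0319). With ranks averaged over the replicates' own lists (15 such genes of 869) the mean was 71.7 (permutation, adjusted p = 0.0346), and the call was lost without replicate 1 (63.9, adjusted p = 0.345), replicate 2 (65.6, adjusted p = 0.0763) or replicate 3 (65.5, adjusted p = 0.144).

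By chromosome, the mitochondrial genome and the X chromosome took the largest shares of the reproducible peaks. Over all 7 chromosomes, the mitochondrial share was 21.8%, and 0 of the other pooled peaks were mitochondrial, since the list is the top of the pooled list and holds all 24. Chromosome V held 8 peaks (7.27% against 20.7%, Fisher's exact test, adjusted p = 6.97e-04) and chromosome II 7 (6.36% against 14.99%, adjusted p = 0.0231). These calls depended on the peaks taken. In the upper part of the list by signal, V (exact test, adjusted p = 0.0530) and II (0.0776) did not pass, while lower shares on I (0.0451) and IV (0.00754) did. That part holds all 24 mitochondrial peaks, which lower the share of every nuclear chromosome. In the strongest 500 pooled peaks V (exact test, adjusted p = 2.16e-04) and I (0.0198) passed and II did not (0.222). The X share, 30 of 110 (27.3% against 19.7%), did not pass (exact test, adjusted p = 0.0754). Among the 86 nuclear peaks it did, at 34.9% (exact interval 24.9 to 45.9, adjusted p = 0.00582). In that comparison chromosome III held 21 peaks (24.4% against 14.5%, exact test, adjusted p = 0.0277; 14.8% in the strongest 500 pooled peaks, adjusted p = 0.897) and chromosome V was again lower (9.30%, adjusted p = 0.0214), while chromosome II no longer passed (8.14%, adjusted p = 0.140). Replicates were uneven: of the 86 strongest nuclear peaks of each replicate, 26, 23, 16 and 32 lay on X in replicates 1 to 4 (exact test, adjusted p = 0.0391, 0.139, 0.775 and 1.28e-04). These p-values were adjusted over the 4 replicates for X alone, and not over chromosomes.

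**Figure D4:**
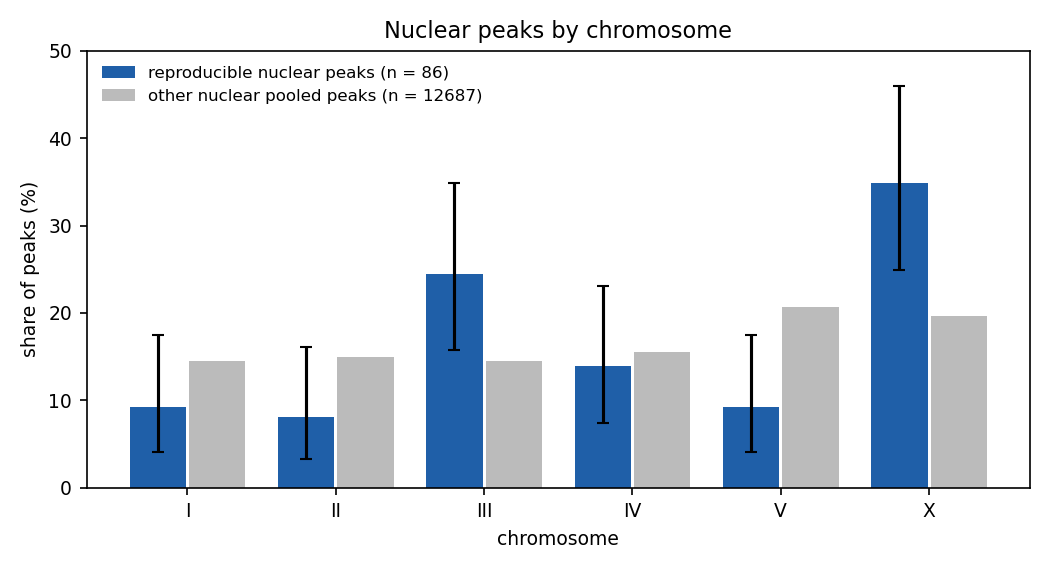
Share of nuclear peaks on each chromosome (percent, vertical), for 86 reproducible peaks (blue, with exact 95% intervals) and the 12687 other pooled peaks (grey). X holds 34.9% of the reproducible and 19.7% of the other peaks.

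SIX-type motifs were rare at the summits. TCAGGTTTC, the MEF3-type site of SIX-family proteins, occurred with up to 1 mismatch at 1 of 109 summits against a flank mean of 3.5 (planned exact sign test, p = 0.0703; exact permutation of windows, p = 0.390). TGATAC occurred at 2 of 109 summits against a flank mean of 2.50 (sign test, p = 0.453; exact permutation of windows, p = 1). Rearranged motifs were at least as frequent in 79 and 74 of 100 rearrangements. The remaining peak, in ND6 at the start of the mitochondrial genome, had no full flank.

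Sequences rich in G and C marked the summits instead. Over all 6-mers, the planned exact sign test called 126, with 5 higher and 121 lower at the summit. The exact permutation of windows, which does not favour the flanks, called 37, with 24 higher and 13 lower, and among the 86 nuclear peaks 46, with 26 higher and 20 lower. The nuclear 6-mers that were higher held 4.12 G or C bases on average and those that were lower 0.600. The top nuclear 6-mers were CGTCTC (23 peaks against a flank mean of 3.5, adjusted p = 2.28e-04), ACGCAG (18 against 2.00, adjusted p = 0.00117), ACACGC (15 against 1.00, adjusted p = 0.00233) and CCTGCG (10 against 0, adjusted p = 0.00587), all by the exact permutation.

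The region of the tagged gene held few peaks close to the gene, and this depended on the width taken. Within 20 kb of unc-39 (V, 14373074 to 14375881) the pooled list held 3 peaks, the 21.9th percentile of windows of that width, and the strongest, at signal 32.7, ranked 383. The replicates held 4, 4, 2 and 4 peaks, at percentiles of 2.93, 2.50, 9.77 and 2.63. Within 10 kb no list held a peak, which for the pooled list is the 5.12th percentile and for replicates 1 to 4 percentiles of 0.672, 0.592, 4.06 and 0.637. Within 50 kb the pooled list held 15 peaks, the 67.6th percentile, and the replicates lay at percentiles of 21.5 to 39.7. Around unc-119, the marker gene of the strain (III, 10902641 to 10908935), the pooled list held 3 peaks within 20 kb, the 18.3rd percentile, and the replicates lay at percentiles of 20.7, 87.2, 7.54 and 38.2.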

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

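The values in this part were singled out after the lists had been described, by the distance of the farthest replicate from the nearest other relative to the range, over 14 measures; chance singles out about 1 in 20 such measures. The relaxed list of replicate 3 held 13225 peaks, against 29529 to 30000 in the other replicates; the lists of replicates 1 and 2 both end at 30000 peaks, so these counts depend on where the lists end. The median peak width in replicate 4 was 356 bp, against 396 to 400 bp in the others on ce11, but 380 bp against 376 to 390 bp on ce10, where replicate 4 was not apart. No group label separates these replicates, and no biological explanation was tested.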

How the results depend on the processing

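Values for nuclear peaks only, for the strongest nuclear peaks of each replicate alone, and by permutation of windows were chosen after the data were seen; the rest were planned. Of the settings tried for the main values, 84 were counted as unchanged. These left the direction and the side of the threshold, the count within 1.5 times, or the mean rho within its SD over pairs (0.10). That last rule is wide beside a mean rho of 0.12. In the rest, 6 brought a value past the threshold, 3 took it out, 13 moved it and 1 turned its direction. Where a value moved, the cause was not tested unless the setting itself gives it. The upper part of the list by signal held 55 peaks. The number of peaks in the top 1000 of every replicate, 35 as planned, was 17 with reciprocal overlap, 14 with summits within 100 bp and 15 with nuclear peaks only. It was 40 to 56 when a replicate was left out, 56 being without replicate 2, a change that could only keep or raise the count. In the signal ranks of promoter peaks, 2 lists passed with a window of 2000 bp, the addition being energy metabolism (68.5). With a replicate left out, 0 to 1 lists passed, with ribosomal protein means of 63.9 to 72.2, and the cause was not tested. In the strongest nuclear peaks of replicate 2 alone, 0 ribosomal protein genes had a promoter peak, a count that decides neither way because few other genes had one. The X share passed the threshold at 28.6% in the strongest 500 pooled peaks and 34.9% with nuclear peaks only, adjusted over chromosomes. It also passed at 30.2% and 37.2% in replicates 1 and 4 alone, where the adjustment ran over the 4 replicates. It did not pass at 26.7% and 18.6% in replicates 2 and 3 alone (adjusted exact p = 0.139 and 0.775), nor at 21.8% in the upper part of the list (adjusted exact p = 0.856), which holds all 24 mitochondrial peaks. SIX-type motifs in the strongest 500 pooled peaks, 9 and 11, fell below the flanks by the sign test, which favours flanks, and not by permutation. The 6-mers called were 762 in the strongest 500 by the sign test, 694 of them lower at the summit, against 319 by permutation, 190 higher and 129 lower; in the reproducible list permutation called 37. The percentile of the unc-39 region, 21.9 as planned, was 5.12 with 10 kb and 67.6 with 50 kb. In the upper part of the list, 1.82% of summits lay near non-coding genes only, a share lowered by the 24 mitochondrial peaks it holds. Leaving out a replicate gave 12.1% to 17.1% for the mean overlap of pairs and 0.06 to 0.19 for the mean rho. Results from the pooled list could not be remade without a replicate. No paired analysis was possible because there is 1 group. Read depth is unknown, so its effect on these lists was not assessed.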

Other observations

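In this part the small RNA classes, the recruitment motif and its settings, the covered share of the mitochondrial genome, the tRNA test, the limits on peaks with either SIX-type motif, the share of the motif among other X peaks, and all GC tests were chosen only after the patterns were seen. Small RNA genes lay close to reproducible nuclear peaks more often than to other pooled peaks. Within 300 bp of the summit there was an snRNA gene at 5 of 86 peaks (5.81%) against 0.189% of the others (odds ratio 32.6, Fisher's exact test, adjusted p = 7.72e-06 over 6 classes). Of these, 4 were genes for the SL2 spliced leader, which is joined to downstream genes of operons: sls-2.1 (summit at II, 5844858, signal 84.5), sls-2.4 (I, 4172187, signal 84.0), sls-2.8 (III, 12250708, signal 58.5) and sls-2.2 (II, 5543605, signal 49.5). tRNA genes lay near 7 peaks (8.14% against 1.65%, adjusted p = 0.00187) and snoRNA genes near 4 (4.65% against 0.820%, adjusted p = 0.0121) by the same exact test. No peak lay near a microRNA, rRNA or piRNA gene, which allows up to 4.20% by the exact interval. Among the other pooled peaks the shares were only 0.315%, 0% and 1.91%, so a count of 0 shows no lower share for these classes.

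On X, some of the reproducible peaks carried a 12-base sequence, TCGCGCAGGGAG, known from sites that recruit the dosage compensation complex to that chromosome. With up to 2 mismatches within 100 bp of the summit it was found at 8 of 30 reproducible X peaks (26.7%, exact interval 12.3 to 45.9), at 0 of 56 reproducible autosomal peaks (Fisher's exact test, p = 1.10e-04) and at 22 of 2499 other X peaks (0.880%, p = 7.03e-10). The allowance of 2 mismatches was chosen with all settings in view; with 1 mismatch it was 6 of 30, 0 of 56 and 4 of 2499, and with 3 mismatches 14 of 30, 10 of 56 and 175 of 2499. The sites included the mom-1 intron (summit 6296574), the peaks nearest to W02H3.3 (11094164), F22H10.2 (16682104) and gtr-1 (806691), the promoters of fbxb-58 (1627163), ins-39 (1345100) and nspc-17 (14525835), and an exon of pks-1 (5429535). Among the 86 strongest nuclear peaks of each replicate, 6, 3, 4 and 8 X peaks held the motif in replicates 1 to 4.

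The excess of X among the reproducible nuclear peaks may come in part from signal at recruitment sites, since 26.7% of the reproducible X peaks held the motif. X held 5 of the 5 strongest nuclear peaks, 6 of 10 and 9 of 20, and of these 2, 2 and 3 held the motif. With up to 3 mismatches it was 4, 4 and 5, adding the peaks nearest to F55G7.5 and ZK899.6 and not K02D3.1, but at that setting 10 of 56 reproducible autosomal peaks held it too. GC content is argued against as the cause of the motif. Reproducible X peaks were richer in GC than other X peaks (45.6% ± 6.20 against 40.4% ± 6.41, SD over peaks, permutation p = 5e-05, the smallest of 20000 draws). Draws of 30 other X peaks matched on GC held 0.509 peaks with the motif on average and 4 at most, against the observed 8. Over 10000 draws the permutation p was 1e-04, the smallest possible. A raised copy number of the whole X would lift other X peaks alike, and only 0.880% of those held the motif. That is the comparison by which the motif was described, so it is no separate evidence against copy number for the 8 peaks. Mappability can differ from place to place and was not tested. Without the motif peaks X held 22 of 78 (28.2% against 19.7%, odds ratio 1.60 against 2.18 with them; exact test, p = 0.0641), a filter that removed X peaks only and so could only lower the share. For the remaining 22 X peaks it cannot be told apart from other causes. Some of these 22, nearest to ets-5, M02F4.2, F46G11.4, C04A11.5 and C16B8.3, lay within 300 bp of a tRNA gene. The higher shares of X and of tRNA genes therefore rest in part on the same peaks and are not separate results. X held 21.3% of pooled peaks from the threshold down to rank 2000, against 19.4% below (exact test, p = 0.0559). That range averages unlike parts, which were not tested one by one. By rank among nuclear peaks, X held 28.5% (exact interval 24.2 to 33.1) from the threshold down to rank 500. From there the share was 22.2% (18.6 to 26.1) down to rank 1000, and then 17.8% (15.5 to 20.3) down to rank 2000. The higher share of X therefore did not end at the threshold but ran on to about nuclear rank 500.

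Whether the mitochondrial peaks reflect the abundance of mitochondrial DNA was left open. They covered 53.1% of that genome, but 24 peaks of this width on so short a genome cover much of it whatever the cause. Binding at SIX-type motifs in most of these peaks is argued against, because either motif was at the summit in 1 of 23 peaks, an upper limit of 21.9%. Binding at a few sites stays open, since TCAGGTTTC was found at 1 summit against a flank mean of 1.5 (exact permutation p = 1) and TGATAC at 0 summits and 0 in the flanks, too few to decide. A comparison with the control would bear on this and was not used here.

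The peaks at ribosomal protein and small RNA genes were not traced to a cause. Signal gathering at highly transcribed genes stays open: 8.14% of nuclear peaks lay near tRNA genes, but these are part of the pattern, and transcription was not measured. Translation and splicing genes decided neither way, with a mean percentile of 49.7 in the pooled list (18 genes, permutation, adjusted p = 0.968) and 72.6 over the replicates' own lists (6 genes, permutation, adjusted p = 0.352). Binding at SIX-type motifs in most nuclear peaks is argued against by an upper limit of 8.15% for peaks with either motif at the summit. Binding through these motifs at a few peaks stays open, with TGATAC at 2 of 86 summits against a flank mean of 2.50 (exact permutation p = 1) and TCAGGTTTC at 0 against 2.00 (exact permutation p = 0.395), and other sequences were searched only as 6-mers. For the ribosomal protein genes, GC content as the whole cause is argued against: draws of other nuclear peaks matched on GC held 0.570 ribosomal protein genes on average, and reached the observed 6 with permutation p = 3e-04 over 10000 draws. No biological explanation by group was tested for any of these patterns, as the design has 1 group.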
